A study of Mus musculus with 12 samples.

How the data were processed

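Small RNA was measured in histone replacement-completed sperm, in which histones have been exchanged for protamines. Sperm were released from the caudal epididymis and vas deferens, briefly sonicated to part heads from tails, and collected through 82% Percoll. Male mice, wild type or heterozygous for Atf7, had received control diet or low protein diet from week 3 to week 12 of age. There were 4 groups of 3 libraries, made from Trizol-extracted RNA with a NEBNext small RNA kit and read at 36 bp paired end on a NextSeq instrument.

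The deposited table lists 2971 unique sequences of 15 to 36 nt (2950 of them 27 to 36 nt) with raw read counts per library. It also holds normalised values which the authors computed by scaling reads to 1 total per library (RPM). These totals, from 2198744 to 6870039 reads, were recovered from the ratio of the deposited counts to the RPM values, and the table holds 97.5 to 98.2% of them. A sequence at 0 counts in a library can have a level of up to 0.437 to 1.36 RPM there, which covers counting error only, since reads without molecular identifiers are not independent molecules. The reads were placed on mm10 according to the submitters' processing notes. The aligner and the counting program are not given in the sources used here. All sample columns were used.

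The table gives no names for the sequences, so each was assigned to a tRNA family by its bases. Taken in order of abundance, each sequence joined the family of the closest sequence already placed, within an edit distance of 2 and with free ends (edlib 1.3.9.post1), or else founded a family. This gave 19 families. Families were named by the anticodon read after the anticodon stem in the fragments long enough to reach it, taking the reading with the most reads that an annotated nuclear tRNA gene carries (11 families), or by a match to an annotated tRNA inside a GENCODE vM21 transcript (Ser-GCT), in all 12. In Val-CAC this was 1 sequence at 33.5 RPM, while GAC, which no such gene carries, was read at 50.2 RPM. A family name need not be the anticodon of each member. The remaining 7 families are called by their first bases. The reading was checked on 10 nuclear tRNA genes inside annotated transcripts, all of which were read correctly. Sequences of nuclear tRNA genes outside annotated transcripts were not used here. No sequence matched any of 22 mitochondrial tRNAs or a miRNA transcript. A sequence was called complete if it starts at the first base in tRNA numbering, extended if it starts before it (2288 and 121 sequences), and trimmed if it starts later (562). Of the extended sequences 105 were His-GTG, a family whose most abundant sequence itself starts before the first base. Complete His-GTG sequences therefore lack a base that this sequence has. The 2409 complete and extended sequences form 1 list.

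The values are counts, so edgeR 4.0.16 quasi-likelihood (R 4.3.3) was used on all 12 libraries with 4 group means, the authors' totals as library sizes and no further scaling. Tests were two-sided, with Benjamini-Hochberg adjustment over all sequences and a threshold of 0.05. Sequences needed a mean of at least 1 RPM, which removed 0. Family totals were tested in the same way over 19 families, with an exact permutation test beside each. The biological coefficient of variation was 0.326. Contrasts were diet in each genotype, genotype on each diet and their interaction. Same-numbered libraries of the groups on control diet deviated together from their group means (r 0.547, 0.143 and 0.522), as a hint from the data and not from the labels, although wild-type replicate 2 went more with heterozygous replicate 1 (0.195). No other groups had a correlation over 0.1 in all 3 numbers. The comparisons, tests, lists, rule for naming sequences and most alternatives were chosen before the data were examined. The plan took tRNA families from names and fragment types from positions given in the table. Both were derived from the bases instead, so the lists of complete and trimmed sequences took their form after the table was opened. The contrasts over both genotypes and over both diets were added later. Named are the 10 largest rises and the 10 largest falls among the called sequences of a comparison, or, where fewer than 20 were called, the called ones and the next by p-value up to 10. The families of the lists are given as well. Some sequences that meet the rule are not reported here. No fold is given where the mean of a group was under the highest of the per-library levels of 3 counts, 1.36 RPM. Sequences named beyond this rule are marked as chosen after their values were seen.

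Lists of sequences were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and with an estimated correlation, and with fry, adjusted over lists and contrasts by Benjamini-Hochberg. They were glycine, glutamate, valine and lysine fragments, the families known to rise in sperm on a low protein diet, and complete and trimmed sequences. Leucine and serine fragments had 3 sequences, too few to test. Mitochondrial tRNAs and microRNA markers of epididymal epithelium, blood and germ cells had 0 sequences in this table. Shares of reads by isotype, start and length were compared by exact permutation of the libraries (20 arrangements for 3 against 3, with a smallest p of 0.1), and over both genotypes or diets by permutation within strata (400 arrangements, with a smallest p of 0.005). For a difference of differences diet was permuted within each genotype, so its p is against no diet effect in either genotype. Of the 67 shares and totals 15 were chosen beforehand, although their isotypes and fragment types were derived from the bases once the table was opened.

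Alternatives were limma on log2 RPM with pseudocounts of 0.1, 1 and 10, DESeq2 1.42.0, a minimum mean of 10 RPM, median-ratio, TMM and quantile scaling, a replicate block, fits on the compared groups only, no abundance trend, and each library left out in turn. Power was tested on simulated data with 200 of 2971 sequences changed 2-fold or 4-fold, each sequence drawn independently. Correlations across libraries used 100000 permutations. Other splits of the samples were enumerated, or 100 drawn where there were more. Shares and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.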

Results

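Glutamate and glycine fragments made up most of the tRNA fragment reads tabulated for mouse sperm whose histones had been replaced. Glu-CTC fragments took 44.5% and Gly-GCC fragments 41.6% of the mean normalised reads over the 12 libraries. His-GTG followed with 4.62%, Glu-TTC with 3.59%, Lys-CTT with 2.69% and Val-CAC with 2.10%. The Gly-GCC fragment GCATTGGTGGTTCAGTGGTAGAATTCTC was at a mean of 116532 RPM (reads scaled to equal library totals). It starts at the first base of the tRNA and ends before the anticodon, as a 5′ fragment. Fragments of this kind are known to be loaded into sperm during passage through the epididymis, and glycine fragments are known from earlier work to respond to a paternal low protein diet.

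The question was how a low protein diet and loss of 1 copy of Atf7, which encodes a stress-responsive transcription factor, alter these fragments in sperm. Wild-type and Atf7 heterozygous males on control diet or low protein diet were compared, with 3 libraries per group. The libraries held 2198744 to 6870039 reads by the authors' totals. Over all sequences pooled, the variance between pairs of replicate libraries was 8.54 to 177 times the variance of counting. Values below are mean ± SD in RPM (n = 3) and log2 fold changes with their standard errors (SE).

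In wild-type males, the fragments that fell on the low protein diet were mostly ones that lacked the first bases of the tRNA. The Glu-TTC fragment CCCACATGGTCTAGCGGTTAGGATTCCTGG, which starts at the second base, went from 794 ± 642 RPM on control diet to 35.5 ± 19.8 RPM on low protein diet (log2 fold change −4.48, SE 0.88). The control-diet libraries were at 1154, 1175 and 52.7 RPM and the low-protein ones at 21.9, 26.4 and 58.2 RPM, so the fold rests on control-diet replicates 1 and 2. Without these replicates of both genotypes it was −0.57 and not called. Its variant CCCATATGGTCTAGCGGTTAGGATTCCTGG went from 459 ± 374 to 22.3 ± 4.76 RPM (−4.36, SE 0.88). The Val-CAC fragment TTTCCGTAGTGTAGTGGTCATCACGCTCGC fell from 21 ± 16.1 to 0.697 ± 0.527 RPM. The Gly-GCC fragment ATGGGTGGTTCAGTGGTAGAATTCTCGT fell from 30.1 ± 24.3 to 1.13 ± 0.856 RPM. Both had too few reads on the low protein diet for a fold.

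Further Glu-TTC fragments lower on this diet were CCCACATGGTCTAGCGGTTAGGATTCCTGA (−4.73, SE 0.91) and CCCATATGGTCTAGCGGTTAGGATTCCTGA (−4.68, SE 1.09). Without control-diet replicates 1 and 2 of both genotypes the first was at −1.03 and the second reversed to 0.03, neither called. For each of the 10 lower fragments named, replicate 3 was the lowest control-diet library. Another 4 called fragments had too few reads on the low protein diet for a fold. These were Glu-TTC CCCACATGGTCTAGCGGTTAGGATTCCTA (30.9 ± 26.0 to 1.16 ± 0.666 RPM), Gly-GCC ATGGGTGGTTCAGTGGTAGAATTCTCGA (6.46 ± 5.95 to 0.116 ± 0.201 RPM), Glu-TTC CCCATATGGTCTAGCGGTTAGGATTCCTA (15.4 ± 13.5 to 0.407 ± 0.0512 RPM) and His-GTG CCGTGATCGTATAGTGGTTAGTACTCTGCT (10.2 ± 10.5 to 0.262 ± 0.232 RPM). The 5 sequences that rose were Glu-CTC fragments of 33 nt. The most abundant of them, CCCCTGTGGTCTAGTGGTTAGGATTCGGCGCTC, rose from 58.0 ± 23.3 to 147 ± 20.9 RPM (1.35, SE 0.32). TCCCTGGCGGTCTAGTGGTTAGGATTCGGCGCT rose from 19.3 ± 2.24 to 40.3 ± 9.94 RPM, and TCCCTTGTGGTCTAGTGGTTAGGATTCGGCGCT from 12.3 ± 1.09 to 23.8 ± 2.18 RPM. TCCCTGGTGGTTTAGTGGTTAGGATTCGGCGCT (1.13) and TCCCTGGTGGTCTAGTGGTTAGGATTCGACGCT (1.05) also rose.

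In all, 75 of 2971 sequences were called between the diets in wild type, 5 higher and 70 lower, by edgeR quasi-likelihood with Benjamini-Hochberg adjustment, and each sequence named has an adjusted p of 0.0486. Of the 70 lower sequences 63 were trimmed at the 5′ end. Over all 562 trimmed sequences the median log2 fold change was −1.65, and 85.6% were negative. Sequences with a complete 5′ end had a median of −0.01. The calls lie close to the threshold: 0 remained with limma and 319 were made with DESeq2, and leaving out any of 10 of the 12 libraries gave 0. Without wild-type control-diet replicate 3, whose trimmed share of 4.36% was the lowest of its group, 577 sequences were called. Without heterozygous control-diet replicate 3 there were 134.

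No tRNA family total was called between the diets in wild type. Glu-TTC came nearest, at 39962 ± 9232 RPM on control diet and 28917 ± 3858 RPM on low protein diet (−0.47, SE 0.20). Val-CAC was at 21549 ± 2867 and 16943 ± 911 RPM, with no overlap between the groups (−0.35, SE 0.19), and an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Both had an adjusted p of 0.390 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment over 19 families. The glycine families that rose on this diet in earlier studies of whole sperm did not differ by more than the spread: Gly-GCC 0.05, Gly-TCC −0.18 and Gly-CCC −0.05. Glu-CTC (0.05), Lys-CTT (0.05) and His-GTG (−0.25) were not called either. The tool called 0 families, with 2 at an unadjusted p under 0.05, and limma called 0.

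In Atf7 heterozygotes the sequences that rose on the low protein diet were 34 nt valine fragments. Val-CAC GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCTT rose from 35.1 ± 5.39 to 139 ± 42.5 RPM (1.99, SE 0.33). Val-CAC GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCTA rose from 19.0 ± 1.13 to 57.8 ± 10.5 RPM (1.60, SE 0.25). By the reading used for names both end on the first anticodon base, which is T and A in place of C. CAC is therefore the name of their family only. The Gly-TCC fragment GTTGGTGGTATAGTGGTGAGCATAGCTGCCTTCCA, trimmed at the 5′ end, fell from 8.21 ± 1.23 to 2.28 ± 0.909 RPM (−1.89, SE 0.32). These 3 were all that edgeR quasi-likelihood called (Benjamini-Hochberg adjusted p 0.0465), against 55 with DESeq2 and 0 with limma. Next in order, and not called (adjusted p 0.180 in the same edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), were trimmed glycine and glutamate fragments. Among them Glu-CTC CCTGTGGTCTAGTGGTTAGGATTCGGCG was at 218 ± 50.8 and 58.5 ± 19.7 RPM and Gly-GCC TTTGTGGTTCAGTGGTAGAATTCTCGCC at 177 ± 37.3 and 44.7 ± 14.7 RPM. Complete Gly-GCC fragments in the same range of p were higher, such as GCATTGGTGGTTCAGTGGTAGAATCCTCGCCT (1.57, SE 0.33) and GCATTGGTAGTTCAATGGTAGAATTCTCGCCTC (1.52, SE 0.32). No call remained without any 1 of 8 libraries: wild-type control-diet replicate 2, the 3 wild-type low-protein libraries, heterozygous control-diet replicates 1 and 2 and heterozygous low-protein replicates 2 and 3. Without heterozygous control-diet replicate 3 there were 71 calls, without wild-type control-diet replicate 3 there were 19 and without replicate 1 of that group 11.

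No family total was called between the diets in heterozygotes by edgeR quasi-likelihood, with 2 at an unadjusted p under 0.05 and 0 by limma. The family that begins GGCTCGTTGG was at 2450 ± 484 RPM on control diet and 1782 ± 35.8 RPM on low protein diet (−0.46, SE 0.19). Its anticodon was not reached by the fragments, so it is named here by its first bases, which are those of proline tRNAs in general knowledge. Glu-TTC was at 41181 ± 10269 and 30847 ± 1163 RPM (−0.42). Gly-GCC was at 400749 ± 86888.7 and 458823 ± 39632 RPM (0.20), His-GTG at −0.43, Glu-CTC at −0.13 and Val-CAC at 0.19 on the log2 scale. Trimmed sequences had a median of −1.11, and 94.5% of them were negative.

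Most sequences called between the diets in wild type had the same sign in heterozygotes (70 of 75), although 0 were called in both. Across sequences, which are not independent replicates, the diet effects correlated with a Pearson r of 0.649 and a Spearman rho of 0.432. The effects are not independent of each other: same-numbered control-diet libraries of the genotypes deviated together from their group means (r 0.547, 0.143 and 0.522), and most trimmed sequences, called or not, were negative in heterozygotes.

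Over both genotypes (6 against 6 libraries, a comparison added after the data were seen) 353 sequences were called, 46 higher and 307 lower, of which 283 were trimmed. The lower ones included Glu-TTC CCCACATGGTCTAGCGGTTAGGATTCCTGG (−3.27, SE 0.59), CCCACATGGTCTAGCGGTTAGGATTCCTGA (−3.37, SE 0.59) and, with too few reads on the low protein diet for a fold, Glu-CTC CCCTGTGGTCTAGTGGCTAGGATTCGGCG (16.9 to 0.900 RPM in wild type, 6.91 to 1.00 RPM in heterozygotes) and Val-CAC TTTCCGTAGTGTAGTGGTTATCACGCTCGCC (10.8 to 0.579 and 5.73 to 1.21 RPM). Gly-GCC ATGGGTGGTTCAGTGGTAGAATTCTCGT and His-GTG CCGTGATCGTATAGTGGTTAGTACTCTGCT were lower as well. Of the 22 lower complete sequences 12 were His-GTG, a family whose most abundant sequence starts before the first base. Complete His-GTG sequences had a median of −0.78 and extended ones of 0.12. The higher ones belonged to several families. Val-CAC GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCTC went from 211 ± 149 to 320 ± 36.0 RPM in wild type and from 212 ± 21.6 to 728 ± 210 RPM in heterozygotes (1.19, SE 0.29). Gly-CCC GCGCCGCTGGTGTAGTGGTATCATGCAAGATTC rose by 1.27 (SE 0.25), Val-CAC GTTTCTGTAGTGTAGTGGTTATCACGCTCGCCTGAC by 1.63 (SE 0.39) and Gly-GCC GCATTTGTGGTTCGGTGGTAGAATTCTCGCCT by 1.25 (SE 0.30). The Val-CAC sequence that rose by 1.63 ends in GAC, so CAC is the name of its family only. Adjusted p-values of the named sequences ran from 0.0199 to 0.0251 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. With limma 0 were called, and without control-diet replicates 1 and 2 of both genotypes 55. In that fit the Glu-TTC folds above shrank to −0.97 and −1.20, neither called, and the median of the trimmed sequences went from −1.38 to −0.32. No call remained without any 1 of wild-type low-protein replicates 1 and 2 and heterozygous low-protein replicates 2 and 3. Without wild-type control-diet replicates 1, 2 and 3 in turn 102, 223 and 714 were called, without those of heterozygotes 56, 160 and 798, and without wild-type low-protein replicate 3 181.

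**Figure D1:**
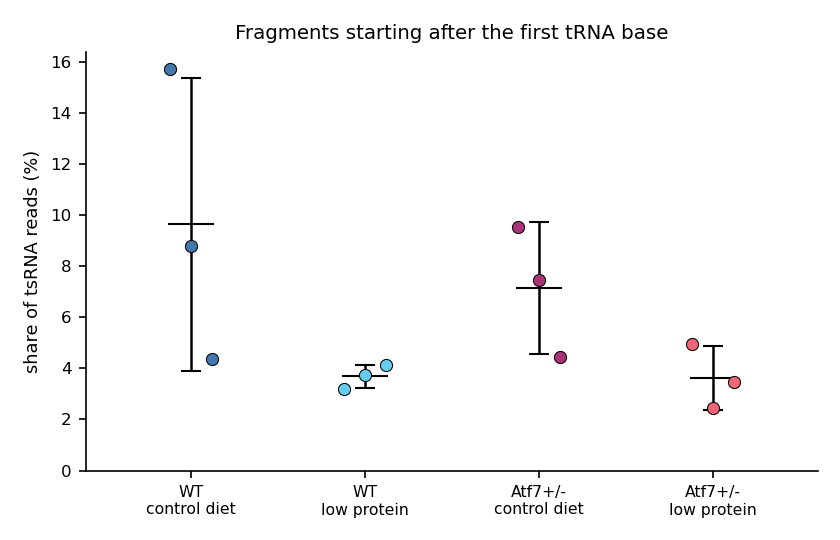
Share of all reads in the table that start at the second base of the tRNA or later, in percent, by genotype and diet. Points are libraries and black bars are mean ± SD (n = 3). The shares run from 2.44 to 15.7%, and the 4 highest belong to control-diet libraries of both genotypes.

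Reads trimmed at the 5′ end made up 9.64 ± 5.74% of the table in wild type on control diet and 3.68 ± 0.468% on low protein diet (exact permutation p 0.1). In heterozygotes the shares were 7.15 ± 2.57% and 3.62 ± 1.26% (exact p 0.2). The control-diet libraries spread widely, at 15.7, 8.81 and 4.36% in wild type and 9.55, 7.47 and 4.44% in heterozygotes. Over both genotypes the difference was −4.74 percentage points (two-sided exact permutation p 0.015, stratified by genotype), with an adjusted p of 0.112 over the 67 shares and totals compared by Benjamini-Hochberg. It was seen within families too: Glu-CTC reads were trimmed in 13 ± 7.21% on control diet and 4.98 ± 0.577% on low protein diet in wild type, Glu-TTC in 11.9 ± 8.55% and 2.43 ± 0.525%, and Gly-GCC in 5.26 ± 3.76% and 2.12 ± 0.309%.

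On control diet no sequence and no family differed between Atf7 heterozygotes and wild type. The sequence with the smallest p was GGCTCGTTGGTCTAGGGGTATGATTCTT at 11 ± 2.24 RPM in wild type and 5.25 ± 0.223 RPM in heterozygotes (−1.07, SE 0.29). Gly-GCC GCATTGGTGGTTCAGTGGTAGAATTCGC was at 32.7 ± 6.41 and 60.5 ± 5.90 RPM (0.89, SE 0.24), and GCATTTGTGGTTCAGTGGTAGAATTCGC at 7.89 ± 1.46 and 14.8 ± 4.15 RPM (0.92, SE 0.27). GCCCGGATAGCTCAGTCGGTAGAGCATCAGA, grouped in the Lys-CTT family, was at 44.3 ± 12.4 and 98.1 ± 38.1 RPM (1.15). It differs from the founding sequence of that family and ends before the anticodon, so its own anticodon was not read. Gly-GCC GCATTGGTGGTTCAATGGTAGAATTCTCGT was at 11.7 ± 4.06 and 5.24 ± 1.11 RPM (−1.19). By edgeR quasi-likelihood 0 of 2971 sequences passed, with 125 at an unadjusted p under 0.05, and DESeq2 and limma called 0. With the replicate number as a block in a fit on the 6 control-diet libraries, chosen after the values were seen, 1 was called: His-GTG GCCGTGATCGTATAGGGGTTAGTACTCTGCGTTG, at 39.7 ± 32.7 RPM in wild type and 9.45 ± 6.95 RPM in heterozygotes. Its log2 fold change was −1.97 (SE 0.38, adjusted p 0.0202 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment) with the block and −2.01 (SE 0.90, adjusted p 1.00) without it in the same 6 libraries. All other sequences named have a Benjamini-Hochberg adjusted p of 0.965 in the edgeR quasi-likelihood test of all libraries. Among families the GGCTCGTTGG family (−0.36), Ser-GCT (−0.49) and the family that begins GCCCGGATGA (−0.31) had an adjusted p of 0.571 by the same edgeR quasi-likelihood and Benjamini-Hochberg procedure. It called 0 families, 0 at an unadjusted p under 0.05, and limma called 0.

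On the low protein diet, heterozygotes had less of a pair of families than wild type. All 3 heterozygous libraries on this diet were deeper (4828916 to 6870039 reads) than all 3 wild-type ones (2278880 to 2874170 reads), so depth is not separated from genotype in this comparison. The GGCTCGTTGG family fell from 3227 ± 214 RPM in wild type to 1782 ± 35.8 RPM in heterozygotes (−0.86, SE 0.19, adjusted p 0.00379 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Ser-GCT, at a far lower level, fell from 109 ± 11.9 to 57.9 ± 4.63 RPM (−0.92, SE 0.29, adjusted p 0.0407 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment). All 3 heterozygous libraries lay below all 3 wild-type libraries in both families (exact permutation p 0.1 each, the smallest possible). The 3 Ser-GCT sequences match a gene on chromosome 13 of GRCm38 (22050686 to 22050767) that lies antisense to an exon of Gm48356, 1 of 8 annotated Ser-GCT genes. The GGCTCGTTGG call was kept with each of the 12 libraries left out, and the Ser-GCT call with 5 of them. With limma 1 family was called, and with quantile scaling 0. The GCCCGGATGA family was lower by less and not called (−0.56). Val-CAC was at 16943 ± 911 and 23403 ± 1909 RPM (0.47, SE 0.19, exact permutation p 0.1) and Val-TAC at 333 and 433 RPM (0.38); neither was called. Gly-GCC was at 391535 ± 14640.5 and 458823 ± 39632 RPM (0.23) and Glu-CTC at 461652 ± 5467.69 and 400501 ± 25201.6 RPM (−0.21), also not called. Glycine fragments took 40.1 ± 1.46% of the table in wild type and 47.0 ± 3.98% in heterozygotes, and glutamate fragments 50.0 ± 0.167% and 44.0 ± 2.70% (exact permutation p 0.1 each).

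**Figure D2:**
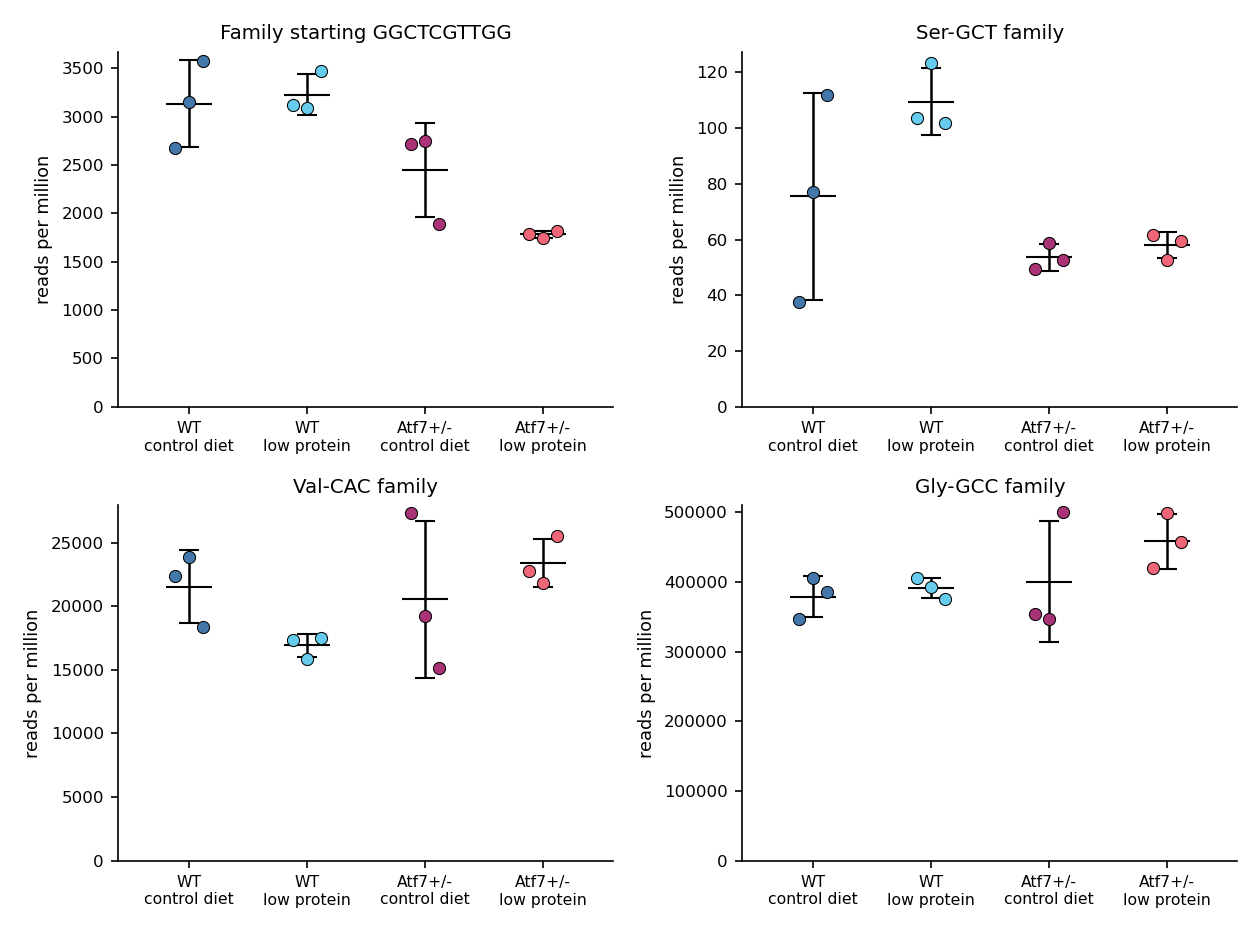
Totals in RPM of 4 tRNA families (GGCTCGTTGG, Ser-GCT, Val-CAC and Gly-GCC) by genotype and diet. Points are libraries and black bars are mean ± SD (n = 3). On the low protein diet the 3 heterozygous libraries lie below the 3 wild-type libraries for GGCTCGTTGG and Ser-GCT.

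Among single sequences, 3 of 1098 Gly-GCC and 1 of 185 Val-CAC sequences were called higher in heterozygotes on the low protein diet. Gly-GCC GCATTGGTGGTTCAGTGGTAGAATTCTCGG rose from 51.5 ± 6.17 RPM in wild type to 155 ± 31.5 RPM (1.59, SE 0.29). Gly-GCC GCATTGGTGGTTCAGTGGTAGAATTCGC rose from 33.8 ± 6.68 to 92.9 ± 16.4 RPM (1.46, SE 0.25), and GCATTTGTGGTTCAGTGGTAGAATTCGC from 7.41 ± 0.471 to 23.7 ± 3.40 RPM (1.68, SE 0.27). Val-CAC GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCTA, for which CAC is the family name only, rose from 21.4 ± 2.12 to 57.8 ± 10.5 RPM (1.44, SE 0.25). Gly-TCC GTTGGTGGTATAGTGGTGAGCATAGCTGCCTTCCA fell from 11.1 ± 2.27 to 2.28 ± 0.909 RPM (−2.30, SE 0.32). Glu-CTC CTGTGGTCTAGTGGTTAGGATTCGGCG fell from 92.5 ± 1.19 to 41.9 ± 6.89 RPM (−1.14, SE 0.21). These 6 calls (4 higher, 2 lower) had adjusted p-values of 0.0211 to 0.0463 by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Not called were Glu-CTC GCCCTGGTGGTCTAGTGGTTAGGATTCG (−1.16), Gly-GCC GCATTGGTGGTTCAGTGGTAGAACTCTCGT (1.53), GCATCGGTGGTTCAGTGGTAGAATTCTCGT (1.32) and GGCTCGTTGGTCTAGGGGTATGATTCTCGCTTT (−1.21, 565 ± 83.5 and 245 ± 6.87 RPM).

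The count depended on which libraries set the spread. It was 0 without any 1 of the wild-type low-protein libraries, heterozygous low-protein replicates 2 and 3 or heterozygous control-diet replicate 2, and 2 without heterozygous control-diet replicate 1. It was 30 and 22 without wild-type control-diet replicates 3 and 1, and 16 without heterozygous control-diet replicate 3. A fit on the 6 low-protein libraries alone called 372 sequences (248 higher, 124 lower), DESeq2 called 101, and limma 6. In the fit on those 6 libraries Gly-GCC had 181 higher and 16 lower sequences, Val-CAC 39 and 0, Glu-CTC 9 and 62, and the GGCTCGTTGG family 0 and 15. His-GTG had 1 higher and 13 lower, Lys-CTT 0 and 6, and Ser-GCT 0 and 3. Chosen after the values were seen, examples are Val-CAC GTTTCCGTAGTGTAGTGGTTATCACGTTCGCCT, higher at 1257 RPM in wild type and 2173 RPM in heterozygotes (0.79, SE 0.13), and Lys-CTT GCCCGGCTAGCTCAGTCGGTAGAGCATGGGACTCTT, lower at 1444 and 717 RPM (−1.01). His-GTG GGCCGTGATCGTATAGTGGTTAGTACTCTG was lower at 4613 and 2132 RPM (−1.11), and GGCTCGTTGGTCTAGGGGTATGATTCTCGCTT at 530 and 231 RPM (−1.20). In that fit the calls among complete Gly-GCC sequences differed between those under 34 nt and longer ones, which was not tested. They were not graded by length, with 19 of 231 higher at 28 nt, 86 of 217 at 30 nt and 9 of 194 at 31 nt. The other lower Gly-GCC calls were trimmed sequences, and Gly-TCC had 8 higher and 6 lower. Of 950 complete Gly-GCC sequences under 34 nt, 181 were higher and 0 lower, whereas of 19 with 34 nt or more 0 were higher and 6 lower. The lower ones were 4 of 10 at 35 nt and 2 of 2 at 36 nt, with 0 of 7 at 34 nt, and the median of the 19 was −0.14. The 35 nt sequence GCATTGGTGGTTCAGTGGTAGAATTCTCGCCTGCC was at 3294 ± 216 RPM in wild type and 1204 ± 144 RPM in heterozygotes (−1.45, SE 0.13), while the 30 nt GCATTGGTGGTTCAGTGGTAGAATTCTCGC was at 32186 ± 693 and 48678 ± 8258 RPM (0.60).

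Over both diets (6 against 6 libraries, added after the data were seen) the same families were lower in heterozygotes. The GGCTCGTTGG family had a log2 fold change of −0.61 (SE 0.13, adjusted p 0.00362) and Ser-GCT of −0.70 (SE 0.20, adjusted p 0.0234) by edgeR quasi-likelihood with Benjamini-Hochberg adjustment. Gly-GCC GCATTTGTGGTTCAGTGGTAGAATTCGC (1.30, SE 0.19) and GCATTGGTGGTTCAGTGGTAGAATTCGC (1.17, SE 0.17) rose, and Gly-TCC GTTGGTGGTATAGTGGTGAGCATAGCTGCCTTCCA fell (−1.39, SE 0.22). No other sequence was called; the GGCTCGTTGG fragment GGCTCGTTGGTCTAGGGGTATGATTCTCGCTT was at −0.82 (SE 0.17) and Ser-GCT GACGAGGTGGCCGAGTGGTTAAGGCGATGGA at −0.94 (SE 0.20). DESeq2 called 33. The edgeR calls were 0 without any 1 of 7 libraries, and 17 and 16 without heterozygous control-diet replicate 3 and wild-type control-diet replicate 1.

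The smallest p-values for a difference in diet effect between the genotypes belonged to glycine fragments of 30 nt, but no sequence passed. Gly-GCC GCATTGGTGGTTCAATGGTAGAATTCTCGT had an interaction of 2.58 (SE 0.49) on the log2 scale, GCATCGGTGGTTCAGTGGTAGAATTCTCGT of 1.86 (SE 0.36) and GCATTGGTGGTTCAGTGGTAGAATTCTCGG of 1.89 (SE 0.40). GCATTGGTGGTTCAGTGGTAGAACTCTCGT was at 1.85, GCGTTGGTGGTTCAGTGGTAGAATTCTCGT at 1.41 and Val-CAC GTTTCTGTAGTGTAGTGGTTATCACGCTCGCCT at 1.99. Gly-TCC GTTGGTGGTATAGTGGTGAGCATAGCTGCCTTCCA had a negative interaction of −1.82 (SE 0.43). By edgeR quasi-likelihood 0 sequences were called (292 at an unadjusted p under 0.05, lowest Benjamini-Hochberg adjusted p 0.249), limma called 0 and DESeq2 3. Without wild-type control-diet replicate 3 there were 39 calls, 37 of them positive. Among families Val-CAC had an interaction of 0.53 (SE 0.27) and the GGCTCGTTGG family of −0.50 (SE 0.26). By edgeR quasi-likelihood 0 families were called, 0 at an unadjusted p under 0.05, with a lowest Benjamini-Hochberg adjusted p of 0.692, and limma called 0.

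**Figure D3:**
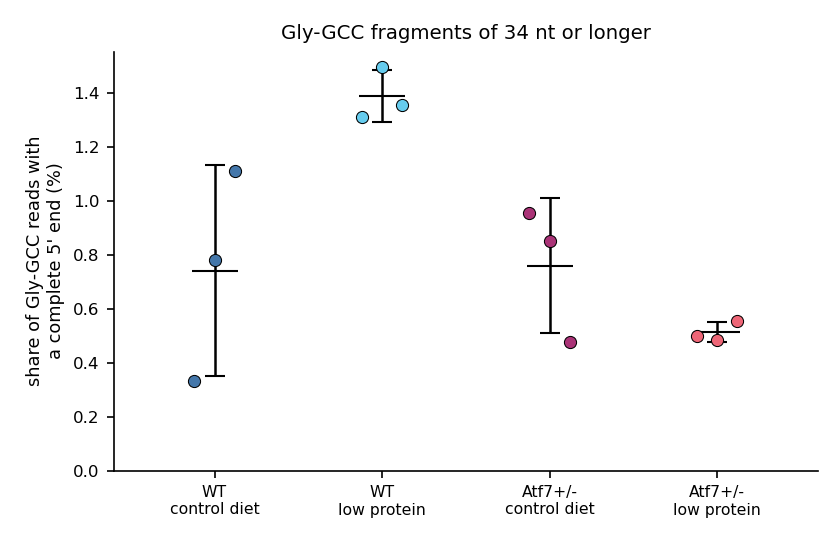
Complete Gly-GCC reads of 34 nt or more as a percentage of complete Gly-GCC reads, by genotype and diet. Points are libraries and black bars are mean ± SD (n = 3). Group means are 0.742, 1.39, 0.761 and 0.514% for wild type on control and low protein diet and heterozygotes on control and low protein diet.

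Long Gly-GCC fragments took a larger share on the low protein diet in the wild-type libraries, while those of heterozygotes overlapped. Complete reads of 34 nt or more were 0.742 ± 0.392% of complete Gly-GCC reads in wild type on control diet and 1.39 ± 0.0960% on low protein diet (exact permutation p 0.1), against 0.761 ± 0.251% and 0.514 ± 0.0378% in heterozygotes (exact permutation p 0.4). The difference of differences was −0.894 percentage points. Its exact permutation p of 0.02 is against no diet effect in either genotype, and did not pass over the 67 measures (Benjamini-Hochberg adjusted p 0.927). With all Gly-GCC reads counted by their 3′ end, control-diet replicate 3 lay nearest to the low-protein libraries in both genotypes. The contrast thus rests mainly on control-diet replicates 1 and 2. Val-CAC reads of 34 nt or more were 2.45 and 3.79% in wild type and 2.64 and 5.59% in heterozygotes on control and low protein diet (exact permutation p over both genotypes 0.02). For Glu-CTC the shares were 1.29 and 2.45%, and 1.30 and 1.74% (exact permutation p 0.01). The share was lower in His-GTG, at 26.0 and 20.4% in wild type and 26.7 and 22.1% in heterozygotes (exact permutation p 0.045). None of the 3 passed the adjustment (0.112, 0.0957 and 0.137 by Benjamini-Hochberg). For Glu-TTC, Gly-GCC, Lys-CTT and Gly-TCC the exact permutation p over both genotypes was 0.09, 0.355, 0.76 and 0.91.

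Of the lists of families, glycine fragments stood higher than other sequences in heterozygotes on the low protein diet against both their control-diet and their wild-type counterparts. The medians of the 1166 glycine sequences were 0.30 for diet in heterozygotes and 0.41 for genotype on the low protein diet. By camera with its preset correlation the adjusted p-values were 4.93e-14 and 3.23e-18. With an estimated correlation the adjusted p-values were 0.117 and 0.103, so neither call held. For diet in wild type the glycine list did not pass (0.859). For genotype on control diet it stood higher by camera with the preset correlation (adjusted p 0.0357). With the estimated one it did not pass (0.754), and its median there was −0.008. Adjusted over the list alone, 5 glycine sequences were higher and 3 lower between genotypes on the low protein diet, against 3 and 1 over all sequences. The list of families known from earlier work to rise in sperm on a low protein diet (Gly, Lys-CTT and His-GTG) holds those 1166 among its 1591 sequences and stood higher in heterozygotes (preset 1.76e-06 for diet, estimated 0.112), and not in wild type (0.886). Its other members did not share this, with medians for diet in heterozygotes of −0.54 for His-GTG and −0.09 for Lys-CTT. Of all 1591 sequences 5 were higher and 1 lower adjusted over the list alone between genotypes on the low protein diet.

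Glutamate fragments stood lower than other sequences in the same comparisons, with adjusted p-values of 5.28e-09 for diet in heterozygotes and 6.53e-13 for genotype on the low protein diet with the preset correlation, and 0.236 and 0.168 with the estimated one. For diet in wild type 26 glutamate sequences were higher and 104 lower adjusted over the list alone, against 5 and 36 over all sequences. All 36 were trimmed, and the list itself did not pass there (median −0.02, preset 0.256). Valine fragments stood lower for diet in wild type (median −0.44, preset 5e-05, estimated 0.512) and higher in heterozygotes against wild type on the low protein diet (median 0.60, preset 1.85e-11, estimated 0.210). Adjusted over the list alone, 0 and 16 valine sequences were higher and lower for diet in wild type, and 2 and 0 in heterozygotes. For the interaction, valine (6.49e-10), glycine (3.87e-09) and the low protein list (5e-05) stood higher and glutamate (7.12e-10) lower with the preset correlation. With the estimated correlation these were 0.215, 0.188, 0.160 and 0.215. The glutamate list had a median of −0.15 and a mean of 0.03 there. The lysine list passed in none of the comparisons.

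Trimmed sequences stood lower than complete ones for diet in wild type (preset 4.9e-35) and in heterozygotes (1.04e-55). With an estimated correlation these were 0.168 and 0.105 for the trimmed list. The list of complete and extended sequences is the rest of the table, so its test is the same contrast seen from the other side. It stood higher at 8.07e-05 and 3.66e-05 and, for genotype on control diet, at 0.0445, but only relative to trimmed sequences, as its medians were −1.93e-04, 0.14 and −0.01. These were the 3 of 35 list tests of the 5 planned comparisons that held with an estimated correlation, of 22 with the preset one. All 3 came from a list that took its form after the table was opened. In the comparisons over both genotypes and over both diets the trimmed list held for diet (0.0488, median −1.38), and its counterpart for diet (4.53e-06) and genotype (0.0228). For genotype on the low protein diet the trimmed list had a median of 0.07 although camera put it lower than other sequences. Fry, which asks whether a list moves on balance in 1 direction, passed 0 of the 35 and none over both genotypes or both diets. Its mixed form, which asks for change in either direction, passed for glycine and for complete sequences between genotypes on the low protein diet (0.0216 each), and for diet over both genotypes in 5 of the 7 lists: glycine, glutamate and trimmed sequences (0.0434 each), valine and the low protein list (0.0436 each).

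In simulated counts, comparisons of 3 against 3 libraries called most changes of 4-fold and few of 2-fold. In simulated counts with the spread of these libraries, 74% of 4-fold and 13% of 2-fold changes were called for diet in wild type, and 84 and 14% for genotype on the low protein diet. For the interaction the recovery was 32 and 0%. With 6 against 6 libraries it was 97 and 54% for diet over both genotypes, and 93 and 58% for genotype over both diets. Sequences were drawn independently, without the deviations that sequences of a library share here, so recovery in the real data may be lower. For diet in wild type the 61 trimmed Glu-TTC sequences had a median log2 fold change of −3.17, and 21 were called. The labels do not state whether the 3 replicates of a group are separate animals, so p-values measure the spread between these samples. Atf7 itself is not measured in a table of tRNA fragments, so the genotype of each library was not checked.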

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

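The check for effects in opposite directions was chosen before the data were examined, and the count over all sequences after the results were seen. For 8 of the 63 named sequences every library moved one way with diet in wild type and every library the opposite way in heterozygotes. The edgeR quasi-likelihood interaction term, adjusted by Benjamini-Hochberg, passed for none of them (adjusted p 0.249 to 0.309), and the opposite direction itself was not tested. The difference between the diet effects is given in RPM, as the change in heterozygotes minus the change in wild type. Of the 8 sequences 6 are Gly-GCC fragments.

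Gly-GCC GCATTGGTGGTTCAGTGGTAGAATTCTCGG differed by 124 RPM, with means of 108 and 51.5 RPM in wild type on control and low protein diet and 87.9 and 155 RPM in heterozygotes. GCGTTGGTGGTTCAGTGGTAGAATTCTCGT differed by 32.3 RPM (40.6 and 25.7 RPM, then 25.4 and 42.7 RPM), and GCATCGGTGGTTCAGTGGTAGAATTCTCGT by 31.4 RPM (30.8 and 14.6, then 21.3 and 36.6 RPM). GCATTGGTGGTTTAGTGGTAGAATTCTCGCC differed by 17.4 RPM, GCATTGGTGGTTCAATGGTAGAATTCTCGT by 12.9 RPM and GCATTGGTGGTTCAGTGGTAGAATTCTAGT by 8.90 RPM. Val-CAC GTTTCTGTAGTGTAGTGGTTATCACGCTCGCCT differed by 14.2 RPM (14.4 and 6.44, then 7.84 and 14.1 RPM). Glu-CTC GCCCTGGTGGTCTAGTGGTTAGGATTCG went the other way, by −18.0 RPM (23.9 and 34.7, then 22.7 and 15.5 RPM).

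Of these 8, 6 had been named for their interaction, so their share among named sequences is no measure of how common the pattern is. Over all 2971 sequences 39 had groups apart in opposite directions, where chance gives 0.5% or 14.9 if sequences were independent, which they are not. Of the 39, 35 were lower on low protein diet in wild type and higher in heterozygotes, and 30 of those were Gly-GCC fragments. No explanation was tested for these sequences.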

How the results depend on the processing

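Chosen after the results were seen were limma with a pseudocount of 1, TMM scaling, leaving out control-diet replicates 1 and 2 of both genotypes together, the fit on complete and extended sequences alone, both contrasts over 6 against 6 libraries, the block on control-diet libraries alone and the alternatives for the trimmed share. Where no cause is given for a difference, the cause was not tested.

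For diet in wild type (75 sequences) calls numbered 0 with limma at each pseudocount (0.1, 1 and 10), with a minimum of 10 RPM, quantile scaling, a fit on the compared groups, no abundance trend, complete sequences alone, and without the 4 control-diet libraries. DESeq2 called 319. Leaving out 1 library gave 0 to 577 (577 without wild-type control-diet replicate 3, 134 without heterozygous control-diet replicate 3, otherwise 0) and 0 to 2 families. For diet in heterozygotes (3 sequences) there were 0, 0 and 1 with limma, 0 with TMM scaling, a fit on the compared groups or no trend, 55 with DESeq2 and 70 without the 4 control-diet libraries, with 2 families called there. Leaving out 1 library gave 0 to 71 sequences and 0 to 3 families, both highest without heterozygous control-diet replicate 3.

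For genotype on control diet (0 sequences, 0 families) 1 library left out gave 0 to 1 of each, and the fit without the 4 libraries 4 families. For genotype on the low protein diet (6 sequences) limma with a pseudocount of 0.1 called 12, median-ratio and TMM scaling 11 each, quantile scaling 3, the replicate block 1, no trend 1, the fit on the compared groups 372, DESeq2 101, the fit without the 4 libraries 370, and complete sequences alone 31. Leaving out 1 library gave 0 to 30. Of the 2 families there, limma with pseudocounts of 0.1 and 1 kept the count at 1 each, quantile scaling gave 0, and the fits on the compared groups and without the 4 libraries 4 each, with 1 to 3 when 1 library was left out. For the interaction (0 sequences) DESeq2 called 3, and leaving out 1 library gave 0 to 39 (39 without wild-type control-diet replicate 3).

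For diet over both genotypes (353 sequences) limma called 0 at each pseudocount, a minimum of 10 RPM left 182, quantile scaling 137, the fit without the 4 libraries 55 with 1 family, and complete sequences alone 0. Leaving out 1 library gave 0 to 798 sequences and 0 to 3 families. For genotype over both diets (3 sequences) DESeq2 called 33, the fit without the 4 libraries 149, complete sequences alone 16, and leaving out 1 library 0 to 17. Of the 2 families limma with pseudocounts of 0.1 and 1 called 1, quantile scaling 0 and the fit without the 4 libraries 8, with 1 to 4 when 1 library was left out. Of 35 list tests in the 5 planned comparisons 22 passed with the preset correlation, 3 with the estimated one and 0 with fry. The other alternatives left each count within 1.5 times its value.

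Of 1198 values that the named, called sequences and families took under these alternatives, 549 stayed called in the same direction, 648 kept the direction and lost the call, and 1 reversed. That was Glu-TTC CCCATATGGTCTAGCGGTTAGGATTCCTGA for diet in wild type, at 0.032 without the 4 control-diet libraries, where 1 library is left in its group and is assumed to vary like the other groups. The GGCTCGTTGG call was lost under quantile scaling only, which keeps no more than the rank of a family total. That family was at rank 7 in 10 of the 12 libraries. The trimmed share difference in wild type (−5.95 points) and heterozygotes (−3.53 points) kept its sign with each library left out, at −8.59 to −2.90 points (−2.90 without wild-type control-diet replicate 1) and −4.89 to −2.33 points (−2.33 without heterozygous control-diet replicate 1). It reversed for genotype on control diet (0.565 without wild-type replicate 1), for genotype on the low protein diet (0.162 without wild-type replicate 3, and 0.530 and 0.00874 without heterozygous replicates 2 and 3), for the interaction (−0.627) and for genotype over both diets (0.252), both without wild-type control-diet replicate 1. With each library left out it ran from −5.13 to 0.565, −0.724 to 0.530, −0.627 to 5.06 and −2.59 to 0.252 points in these comparisons.

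The median log2 fold change of all sequences was −0.10 for diet in wild type and 0.13 under quantile scaling. For genotype on the low protein diet it was 0.11 and moved to 0.01 with median ratios and −0.02 under quantile scaling, and for the interaction from 0.16 to 0.05 with median ratios, so glycine rises there are partly relative to that shift. Same-numbered libraries had r over 0.1 in 6 of 18 pairs (−0.403 to 0.583), 3 of which were the control-diet pairs of the genotypes. With a block on the control-diet libraries alone 1 sequence and 0 families were called between genotypes there, against 0 without it in the same libraries. The SE of that sequence was 0.38 with it and 0.90 without it. The block gave 80 sequences for diet in wild type, 3 in heterozygotes and 356 over both. The alternatives without a filter and with identical sequences kept apart are void, since the filter removed 0 sequences and 0 were identical, and DESeq2 was not run on families. Depth limits rare sequences: 37 had 0 reads in some library, and fragments with a group mean under 1.36 RPM are given no fold.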

Other observations

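The tests of trimmed fragments, the test of long Gly-GCC fragments over all measures and the split of the low-protein libraries were chosen after the results were seen.

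For the lower level of fragments lacking 5′ bases on the low protein diet, scaling by library total is argued against, since the trimmed share within families, which no scaling can move, had a median log2 ratio between diets of −0.90 and was lower in 15 of 15 families (−1.70 to −0.03). General breakdown of RNA would bring short complete fragments along with trimmed ones, and it stays open: over the 12 libraries the trimmed share and the share of complete fragments of 29 nt or less correlated negatively by Pearson r (−0.648, permutation p 0.0235) but not past the threshold by Spearman rho (−0.448, p 0.146). Of the 3 families tested, Glu-CTC (r −0.583, p 0.0462; rho p 0.154) and Gly-GCC (r −0.480, p 0.118) were negative, and Lys-CTT was positive with r 0.692 (p 0.0158; rho 0.566, p 0.0588). Separate handling of control-diet replicates 1 and 2 of both genotypes stays open. Without them the median of the trimmed sequences over both genotypes was −0.32 in place of −1.38. These 4 libraries had the highest trimmed shares and were all on control diet. Leaving them out would shrink the difference whether handling or diet caused it, so this fit cannot decide. Handling and an effect of diet that varies between males cannot be told apart in these 4 libraries, and diet stays open.

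For the lower GGCTCGTTGG family in Atf7 heterozygotes, 2 further edgeR quasi-likelihood fits with Benjamini-Hochberg adjustment were made over both diets. Scaling to the minor families instead of all reads left −0.55 (adjusted p 0.00905), which argues against scaling as the whole cause over both diets. Library total as a covariate left −0.80 (adjusted p 0.0210). This covariate cannot separate depth from genotype. Among heterozygous libraries only control-diet replicate 3 (2198744 reads) was as shallow as wild type (2278880 to 3927919 reads). On the low protein diet all heterozygous libraries were deeper than all wild-type ones. Depth therefore stays open, both over the diets and on the low protein diet. Quantile scaling brought the change over both diets to −0.18 (adjusted p 0.199 by limma with Benjamini-Hochberg adjustment, with 7.26e-05 to 0.199 over the alternatives). It sets totals of equal rank to 1 value, however, and this family was at rank 7 in 10 of 12 libraries. For Ser-GCT, also lower, the change of −0.70 (SE 0.20) became −0.65 (SE 0.25, adjusted p 0.0877) and −0.54 (SE 0.33, adjusted p 0.273) in these edgeR quasi-likelihood fits with Benjamini-Hochberg adjustment. The calls ended mainly because the error grew, so scaling and depth stay open there. Genotype is a candidate explanation for GGCTCGTTGG as a hypothesis, with chance not excluded by the splits of the samples for the count of families, and a difference between litters or handling days was not tested.

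Complete Gly-GCC fragments of 34 nt or more took a larger share on the low protein diet in all 3 wild-type libraries, with overlap between diets in heterozygotes (exact permutation p 0.4). Loss of 5′ bases, which shortens reads, is argued against for the contrast in these libraries. With all Gly-GCC reads counted by the position of their 3′ end the difference of differences was −0.927 points. The group means were 0.817, 1.49, 0.810 and 0.556%. The exact permutation p of 0.015 is against no diet effect in either genotype, and not against equal diet effects. Chance among the 67 measures stays open, with an adjusted p of 0.927 by Benjamini-Hochberg. By 3′ end, the control-diet libraries were at 0.365, 0.836 and 1.25% in wild type and at 0.992, 0.899 and 0.538% in heterozygotes. The low-protein ones were at 1.42, 1.60 and 1.45%, and at 0.546, 0.520 and 0.601%. The contrast thus rests mainly on control-diet replicates 1 and 2, and their handling was not tested for this share. A genotype-dependent place of cleavage is not excluded and could only be tested in further samples.

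The 6 libraries of a comparison make 10 splits with the real one, too few for a share under 0.05. For diet in wild type the real split called 75 sequences and the highest other 0, for diet in heterozygotes 3 and 0, for genotype on control diet 0 and 112, and for genotype on the low protein diet 6 and 0. As many calls as the real split came from 1, 1, 10 and 1 of the 10 splits. For families the real and highest other counts were 0 and 0, 0 and 3, 0 and 1, and 2 and 0, reached by 10, 10, 10 and 1 of 10 splits. The split with 112 calls sets wild-type control-diet replicate 1 and heterozygous control-diet replicates 1 and 2 against the rest, which points to a structure of the samples that genotype does not follow. It keeps same-numbered libraries together for 2 of the 3 numbers, and of the other splits that part all 3 the highest called 9. In the fit on low-protein libraries alone the real split called 372 and the highest other 0.

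Of 100 splits drawn for the larger comparisons, 3 called at least the 353 sequences of diet over both genotypes (highest other 480). That share is under 0.05, but the contrast was added after the data were seen and its count ran from 0 to 798 with 1 library left out, so it is weak evidence against chance. Both higher splits keep control-diet replicates 1 and 2 of both genotypes on 1 side, so the count may reflect those 4 libraries more than diet. For its families the real count was 0 and the highest other 3, and 100 of 100 reached it. For genotype over both diets 5 of 100 splits reached the 3 sequences (highest other 136) and 5 of 100 the 2 families (highest other 5), so chance is not excluded. For the interaction 100 of 100 reached the real count of 0, with a highest other of 354 sequences and 2 families. Splits with 136 and 354 calls, many times the real counts, point to a structure of the samples: the first puts wild-type control-diet replicate 1 with heterozygous control-diet replicates 1 and 2, and the second puts wild-type control-diet replicates 1 and 2 with wild-type low-protein replicate 3.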
